A study of Mus musculus with 2 samples.

How the data were processed

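RNA was measured in 2 samples, 1 preparation of gamma/delta T cells and 1 of CD8+ alpha/beta T cells. Both came from lymph nodes of C57BL/6 mice and were purified by negative selection, per the labels. Each was hybridised to its own Affymetrix MOE430 2.0 expression array, a 1-colour array on which a gene is read by 1 or more probe sets of short oligonucleotides. Biotin-labelled target was made with the 1-cycle protocol, per the labels. The deposited table holds 1 intensity per probe set and array, which the authors computed with MAS5 in Affymetrix Expression Console 1.0, per the submitters' processing notes. The values are linear signals in scaled units. In the deposited values the trimmed mean over all probe sets, with 2% left out at each end, was 500.003 on each array, so both arrays had been scaled to one target before deposit. MAS5 subtracts a mismatch estimate and spreads weak signals widely, so that low intensities carry little order. Detection calls and scanner files were not used here.

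The table holds 45101 probe sets, of which 64 are controls. Gene names came from a platform annotation. It gave 1 symbol to 34958 probe sets and several symbols to 932, and it did not list 9211. The gene identifiers of 34754 of the probe sets with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, and no symbol differed. Probe sets with several symbols or none listed name no gene here, and neither do control probe sets, which was decided after the first gene values were seen. This left 18193 genes. No genome build applies to the values, and no coordinates are given. List members that matched no probe set with 1 symbol were not analysed here.

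The values were used as deposited, because the trimmed means without controls (497.0 for gamma/delta and 496.8 for alpha/beta) lay within the tolerance of 1% set in advance. A gene took the value of its probe set with the highest mean log2 signal over both arrays. The floor was the higher of the arrays' medians over probe sets that are not controls, a signal of 243.3. The 27 probe sets for bacterial transcripts that carried no spike-in signal stayed below it, with a highest signal of 167.2 on the gamma/delta array and 161.8 on the alpha/beta array. Signals under the floor were raised to it before the log2 ratio of gamma/delta to alpha/beta was taken. A gene under the floor on 1 array therefore has only a bound, written as at least N-fold, and a gene under it on both has no ratio. This is read from the probe set used for the gene, and of 6279 genes under the floor on both arrays 137 had another probe set above it on at least 1 array. A gene was called at a ratio of 2-fold or more.

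With 1 array per group there is no replicate, no standard error and no p-value, and the ratios compare these 2 preparations. The only spread within the data is that between probe sets of one gene on the same pair of arrays. Its pooled SD was 0.50 on the log2 scale over 3317 genes with at least 2 probe sets above the floor on both arrays. The depth of an array is not counted in reads, and the number of arrays limits the precision. The labels do not say how many mice each preparation came from.

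Before the data were examined, the floor, the call, 19 gene lists and 7 lists of cell type markers were fixed. For each list the median log2 ratio was set against 10000 random gene lists of the same size, matched in 20 bins of mean signal, and its percentile describes these arrays only. Lists share members. The rule for named genes, also fixed in advance, took Blk and the other Src family kinases, Cd44, Cd8a, Cd8b1, Cd4 and the TCR loci, the 10 genes per direction with the largest ratio among those whose probe sets above the floor on at least 1 array had one sign, and up to 4 members per list with the largest ratio. Members named beyond these were chosen after their values were seen.

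The calls and percentiles were checked on simulated data, a pair of arrays with the real genes' mean signals and normal noise set from the median absolute difference of the real pair at each signal, in which 200 genes were given known ratios. Of the genes set apart by a log2 ratio of 1.5, 77.6% were called in the right direction, and of those set apart by 2 and by 3, 92.9% and 100%. Of the simulated genes with no difference, 10.7% passed the 2-fold call, while 9.74% of the real genes with a ratio did. The noise was set from the pair's own differences, real ones included, so these shares are alike by construction and do not say how many calls are noise. An earlier simulation that counted the noise of an array 2 times was replaced. Of 200 simulated lists of 15 unchanged genes, 5% fell outside the central 95% of random lists. Those lists were drawn at random from the same simulated genes, so about this share follows by construction. Genes that vary together within a real list were not simulated.

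The alternatives were median scaling, quantile normalization and an intensity-dependent loess between the arrays, floors at the 30th and 70th percentile and no floor, the mean over a gene's probe sets, probe sets ending in _x_at, _s_at or _a_at left out, and thresholds of 1.5-, 3- and 4-fold. A floor at the brightest empty bacterial control was added after seeing the data. The predictions against which explanations were tested had bounds, and for 4 of the 8 tests the rule for excluding an explanation was made stricter after the values were seen, as the closing section says at each. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.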

Results

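Naive gamma/delta T cells, labelled as CD44-negative, were compared with naive CD8+ alpha/beta T cells from lymph nodes of C57BL/6 mice, with 1 array for each. The 2 T cell lineages carry different antigen receptors, and the series title concerns Blk, a Src family kinase best known from B cells, and gamma/delta T cells that make IL-17. The median signal was 243.3 on the gamma/delta array and 242.1 on the alpha/beta array. Above the floor of 243.3 lay 22519 and 22439 probe sets. Over 18 probe sets for spiked-in transcripts the median log2 ratio of gamma/delta to alpha/beta was -0.09, with a range from -0.21 to 0.04. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 6.99 for actin on the gamma/delta array and 3.12 on the alpha/beta array. For Gapdh it was 3.06 and 3.24, and for the transferrin receptor 3.97 and 4.47.

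The T cell receptor gamma segments Trgv4 and Trgv1 were at least 51.5-fold and at least 38.8-fold higher in gamma/delta cells, with signals of 12522 and 9449 against 170.4 and 13.7. Cd8a and Cd8b1, the chains of the CD8 coreceptor, were 12.1-fold and 5.74-fold higher in alpha/beta cells. Their signals on the gamma/delta array, 731.1 and 382.3, were still above the floor by the probe sets used. The other probe sets of Cd8a read 273.0, 42.5, 5.80 and 4.92 there, mostly under the floor, and all were higher in alpha/beta cells. Whether the gamma/delta preparation held Cd8a transcript therefore depends on the probe set. Trav9d-3, an alpha segment, was 3.86-fold higher in alpha/beta cells, with a signal of 2482 on the gamma/delta array, also above the floor. Its other probe sets with a ratio were 11.8-fold and 8.02-fold higher in alpha/beta cells, with lower gamma/delta signals of 548 and 494. Cd4 lay under the floor on both arrays. Variable segments belong to families of similar sequence and their probes may cross-hybridise, so these values are uncertain for the single segment. Of the 5 alpha/beta receptor genes with a ratio, Trav9d-3 alone reached 2-fold, and the median was -0.34 at the 19.6th percentile of random lists. Tcra, at least 1.56-fold higher in gamma/delta cells (379.0 against 170.3), and Trbv1, with signals of 14596 and 12892, were not higher in alpha/beta cells. The 1 probe set of Tcra lay under the floor in alpha/beta cells, whose receptor holds an alpha chain, so it may not read that transcript. The list's median includes it. Cd44 had a log2 ratio of 0.32, and its 3 probe sets with a ratio ran from -0.85 to 0.97, so that no direction can be given.

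Across the array, 693 genes were at least 2-fold higher in gamma/delta cells and 468 at least 2-fold higher in alpha/beta cells, out of 11914 with a ratio. Of these, 189 and 105 are bounds. At 4-fold the counts were 81 and 22, and at 8-fold 26 and 3. The largest differences towards gamma/delta, with bounds taken at their value and beside the receptor segments, were in Fos, a component of the AP-1 transcription factor (92.2-fold), Cd163l1, a scavenger receptor family member (at least 36.9-fold), Dntt, the terminal transferase of lymphocyte precursors (26.9-fold), and Dusp5, a MAP kinase phosphatase (21.3-fold). Itgb3, the integrin beta 3 chain (at least 19.3-fold), 5830411N06Rik (at least 17.5-fold), Ifit1, an interferon-induced gene (17.3-fold), and S100a6, a calcium-binding protein (at least 17.2-fold), followed. Towards alpha/beta the largest, among genes whose probe sets had one sign, were Tent5c, a poly(A) polymerase (17.6-fold), and Itga6, the integrin alpha 6 chain (14.4-fold). After Cd8a came Bach2, a transcriptional repressor (6.30-fold), Cd8b1, Slfn1 (5.73-fold), Rras2, a small GTPase (5.56-fold), Bambi-ps1 (at least 5.48-fold), Ms4a6c (5.08-fold) and Btbd11 (4.96-fold). Of the 1161 called genes, 540 had several probe sets with a ratio, and in 202 of these the probe sets disagreed in sign. With probe sets averaged, Itgb3 had a log2 ratio of at least 0.53 and Slfn1 lay under the floor on both arrays. The counts have no replicate check.

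**Figure D1:**
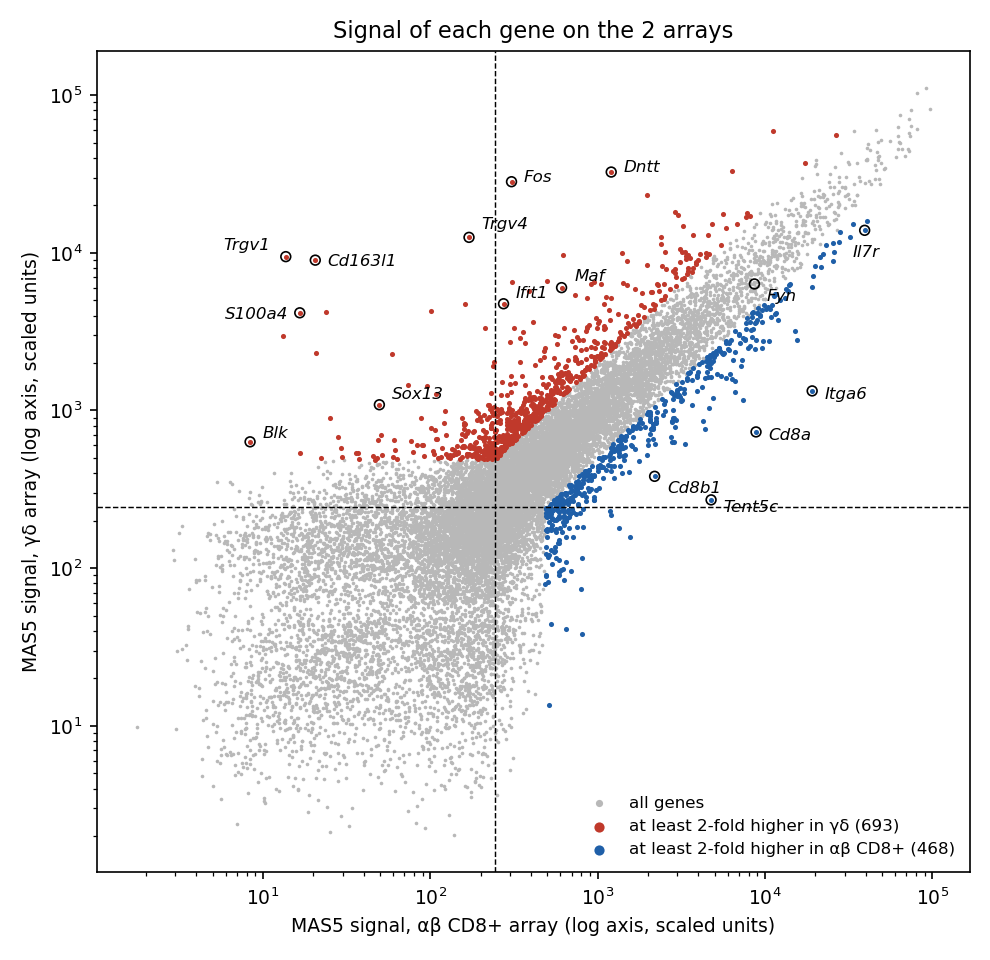
MAS5 signal of each of 18193 genes on the gamma/delta array (vertical, log axis, scaled units) against the alpha/beta CD8+ array (horizontal, log axis), 1 point per gene; dashed lines mark the floor of 243.3, red the 693 genes at least 2-fold higher in gamma/delta and blue the 468 at least 2-fold higher in alpha/beta, both after signals under the floor were raised to it. Trgv4, Trgv1, Cd163l1 and Blk lie under the floor on the alpha/beta array only, and Cd8a and Itga6 lie far to the right of the diagonal.

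Blk had a signal of 632.7 in gamma/delta cells and 8.37 in alpha/beta cells on its 1 probe set, which puts it at least 2.60-fold higher in gamma/delta cells (log2 ratio of at least 1.38). No other measured Src family kinase reached 2-fold. Fyn, which transmits T cell receptor signals, was abundant in both, at 6342 in gamma/delta and 8660 in alpha/beta cells. Yes1 stood at 1517 and 1191, Fgr at 528.5 and 299.5, and Src under the floor on both arrays. The list's median log2 ratio of 0.58 over 4 genes lay at the percentile of 93.1 of random lists. Because the title names Blk, it may have been chosen on these same arrays, and its ratio is then not independent evidence of its direction. With the floor at the 70th percentile the bound on its log2 ratio was 0.50, below the 2-fold call.

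**Figure D2:**
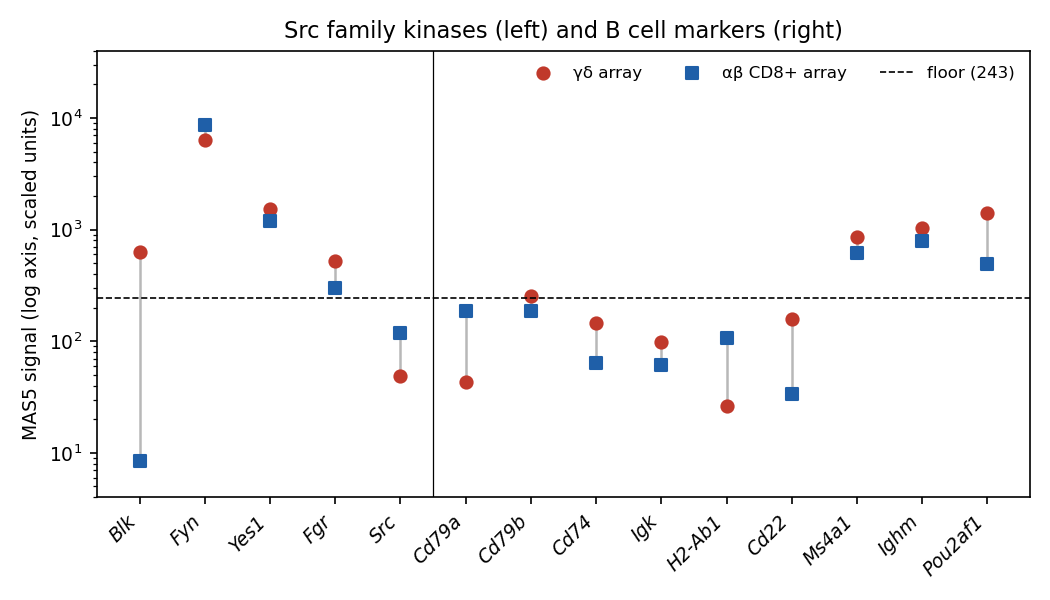
MAS5 signal (vertical, log axis, scaled units) of 5 Src family kinases (left) and 9 B cell markers (right) on the gamma/delta array (red circles) and the alpha/beta CD8+ array (blue squares), 1 value per array from the probe set used for each gene, with the floor of 243.3 dashed. Blk is above the floor on the gamma/delta array only, at 632.7, while Cd79a, Cd74, Igk and Cd22 are under it on both.

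Genes of the IL-17-producing gamma/delta programme were higher in gamma/delta cells as a list. Of 22 members with a ratio, 9 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio of 0.69 lay at the 100th percentile of random lists, and was 0.42 with the floor at the 70th percentile. After Cd163l1 and 5830411N06Rik the largest were Maf, a bZIP transcription factor (9.86-fold), and Sox13, an HMG-box factor of the gamma/delta lineage (at least 4.47-fold). Sox4 (3.95-fold), Tmem176a (3.41-fold), Blk, the chemokine receptor Ccr6 (2.10-fold) and the interleukin 1 receptor Il1r1 (at least 2.01-fold) completed the 9. With the floor at the 70th percentile the calls of Blk, Ccr6 and Il1r1 were lost. Their gamma/delta signals of 632.7, 560.0 and 488.8 lay less than 2-fold above it. Il17a itself had signals of 521.2 and 297.8, a log2 ratio of 0.81. Of the 22 members, 14 also belong to other lists. The 5 probe sets of Maf with a ratio were all higher in gamma/delta cells, by log2 ratios from 0.32 to 3.30, and the 2 of Sox4 ran from 0.02 to 1.98. With probe sets averaged, Sox4 lay under the floor on both arrays.

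Among 23 transcription factors of T cell lineages, 5 were at least 2-fold higher in gamma/delta cells and 1 at least 2-fold lower. The median log2 ratio of 0.41 (bootstrap interval -0.08 to 0.80) lay at the 99.5th percentile. Beside Maf, Sox13 and Sox4 the higher ones were Ikzf2 (2.30-fold) and Runx3 (2.07-fold). Lef1, which acts with beta-catenin in naive T cells, was 2.37-fold higher in alpha/beta cells. With probe sets averaged the percentile was 96.6 and Ikzf2 had a log2 ratio of 0.58.

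Interferon-stimulated genes were the list with the largest shift after the receptor genes. Of 16 members with a ratio, 11 were at least 2-fold higher in gamma/delta cells and 0 lower, with a median log2 ratio of 1.63 at the 100th percentile. Beside Ifit1 these included Rsad2 (10.7-fold), Usp18 (at least 9.46-fold) and Rtp4 (8.82-fold). Ifit2 and Igtp had log2 ratios of -0.10 and -0.06.

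Immediate early and heat shock genes were higher in gamma/delta cells as 1 joint list. Of 13 members with a ratio, 5 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.60 at the 99.9th percentile. With no floor the median was 0.35 at a percentile of 95.8, and without probe sets ending in _x_at, _s_at or _a_at it was 1.31. The 5 were Fos, Jun (6.02-fold), Dusp1 (5.22-fold), Junb (4.74-fold) and Fosb (at least 4.06-fold). The other immediate early genes Zfp36, Btg2 and Ier2 had log2 ratios of 0.68, 0.04 and -0.17, and Atf3 and Ier3 lay under the floor on both arrays. The heat shock genes Hspa1b, Hsp90aa1, Hsph1, Dnajb1 and Hspa8 had log2 ratios of 0.60, 0.41, 0.29, 0.07 and -0.25. Targets of strong T cell receptor signals went both ways. Egr1 (5.74-fold), Nr4a1 (at least 3.97-fold) and Bhlhe40 (at least 2.11-fold) were higher in gamma/delta cells, Nr4a3 (5.39-fold) and Egr2 (2.09-fold) were higher in alpha/beta cells, and the median log2 ratio over 13 genes was 0.29 at the 89.7th percentile. The probe sets of Nr4a3 disagreed, with log2 ratios of -2.43 and 0.20, and their average lay under the floor on both arrays. With the floor at the 70th percentile Bhlhe40 had a bound of 0.20. The 3′ to 5′ ratio of actin was also higher on the gamma/delta array, at 6.99 against 3.12. Those of Gapdh (3.06 against 3.24) and the transferrin receptor (3.97 against 4.47) were slightly lower there.

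Genes of naive and recirculating T cells went both ways, with 6 of 13 members above 0 and 7 below. Of these, 5 were at least 2-fold lower in gamma/delta cells and 1 higher, and the median log2 ratio of -0.43 (bootstrap interval -1.36 to 0.16) lay at the 1.29th percentile. Bach2, Il7r, the interleukin 7 receptor (2.84-fold), Klf3 (2.72-fold), Satb1 (2.56-fold) and Lef1 were lower, and Igfbp4 was 2.92-fold higher, with probe sets from -0.43 to 2.14 on the log2 scale. The homing genes S1pr1 and Klf2 had log2 ratios of 0.29 and 0.16, and Ccr7 had one of -0.56. After quantile normalization and after loess the list lay at the 5.88th and 6.90th percentile.

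Of 16 effector and memory genes with a ratio, 4 were at least 2-fold higher in gamma/delta cells and 0 lower, with a median log2 ratio of 0.49 at the 99.6th percentile. They were S100a6, S100a4 (at least 17.1-fold), Lgals1, which encodes galectin-1 (5.21-fold), and Anxa2 (2.77-fold). Without probe sets ending in _x_at, _s_at or _a_at the percentile was 93.0. Anxa2 had a bound of 0.86 with the floor at the 70th percentile and no ratio with probe sets averaged. Type 1 and cytotoxic genes did not stand apart as a list (median 0.40 over 14 genes, 94.4th percentile). The granule genes Nkg7 (6.04-fold) and Gzma (at least 5.93-fold) were higher in gamma/delta cells, while Gzmb and Tbx21 lay under the floor on both arrays and Ccl3 had a log2 ratio of -0.83. Of 7 NK receptor and adaptor genes with a ratio, Hcst, an adaptor of NK receptors, was 2.48-fold higher in gamma/delta cells and Klrd1, which encodes CD94, was 4.32-fold higher in alpha/beta cells. The median of -0.09 lay at the 34.9th percentile.

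Chemokine receptors and integrins differed in both directions. Of 18 with a ratio, 7 were at least 2-fold higher in gamma/delta cells and 2 at least 2-fold lower. The median log2 ratio of 0.50 (bootstrap interval -0.21 to 1.32) lay at the 99.7th percentile, and at 94.7 when probe sets were averaged. Higher were Itgb3, the gut-homing receptor Ccr9 (11.8-fold), Itgae, the alpha E integrin chain (7.33-fold), its partner Itgb7 (3.91-fold), Itgal (2.71-fold), Itgb2 (2.31-fold) and Ccr6. Lower were Itga6 and Itga4 (2.58-fold). Itgb3 lost its 2-fold call with probe sets averaged. The 5 probe sets of Ccr9 ran from a log2 ratio of -0.20 to 3.56, and without those ending in _x_at, _s_at or _a_at its value was -0.20. In the list of CD8 T cell identity genes, Itgae and Runx3 were higher in gamma/delta cells, while Cd8a, Cd8b1, Actn1 (3.14-fold) and Satb1 were lower. Its median of 0.33 (94.0th percentile) and its mean of -0.32 differed in sign.

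Cytokine receptors as a list did not stand apart (median 0.17 over 22 genes, 77.8th percentile). Il27ra (3.04-fold), Ifnar2 (2.32-fold), Il12rb1 (2.29-fold), Il10ra (at least 2.01-fold) and Il1r1 were higher in gamma/delta cells and Il7r lower. The probe sets of Ifnar2 ran from -0.28 to 1.22, and with the floor at the 70th percentile Ifnar2 and Il12rb1 had bounds of 0.59 and 0.78. The gamma/delta signals of Il10ra and Il1r1, 489.9 and 488.8, lay less than 2-fold above that floor, so their calls were lost too. Of 18 costimulation and TNF family genes with a ratio, Tnfsf11, which encodes RANKL (4.91-fold), Btla (at least 3.72-fold) and Tnfrsf18 (at least 2.25-fold) were higher in gamma/delta cells. Cd28 was 2.63-fold higher in alpha/beta cells, and the median of 0.17 lay at the 85.3th percentile. Tnfsf11 lay under the floor on both arrays with probe sets averaged, and Tnfrsf18 had a bound of 0.29 with the floor at the 70th percentile.

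Of 22 genes of proximal T cell receptor signalling, 3 were at least 2-fold higher in gamma/delta cells and 3 lower, with a median of 0.20 at the 88.7th percentile. The phosphatase Ptpn6 (3.05-fold), the adaptor Lat (2.35-fold) and Cd3g (2.31-fold) were higher, and Ptpn6 had bounds of 0.97 with the floor at the 70th percentile and 0.80 with probe sets averaged. The phosphatase Ptpn22 (2.14-fold) and the kinases Txk (2.11-fold) and Tec (2.10-fold) were lower. The alpha/beta signals of Txk and Tec, 886.8 and 824.2, lay less than 2-fold above the 70th percentile floor, under which their calls were lost. Cell cycle genes had a median log2 ratio of -0.33 (bootstrap interval -0.69 to 0.15) over 17 genes at the 2.25th percentile. In this list, 4 were at least 2-fold lower in gamma/delta cells (Stmn1, Ccna2, Mcm6 and Mcm3, from 2.88- to 2.14-fold) and 0 higher, while Mki67 and Top2a had log2 ratios of 0.26 and 0.44. The probe sets of Ccna2 and Mcm3 disagreed in sign, with probe sets averaged Ccna2, Mcm3 and Mcm6 had log2 ratios of -0.35, -0.43 and -0.85, and the percentile was 14.1 with the floor at the 30th percentile. In the glycolysis list Slc2a3 (2.10-fold) and Pgam1 (2.04-fold) were higher in alpha/beta cells, Ldha had a log2 ratio of 0.91, Slc2a3 had a bound of -0.09 with probe sets averaged, and the list's median was -0.11 at the 29.9th percentile.

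**Figure D3:**
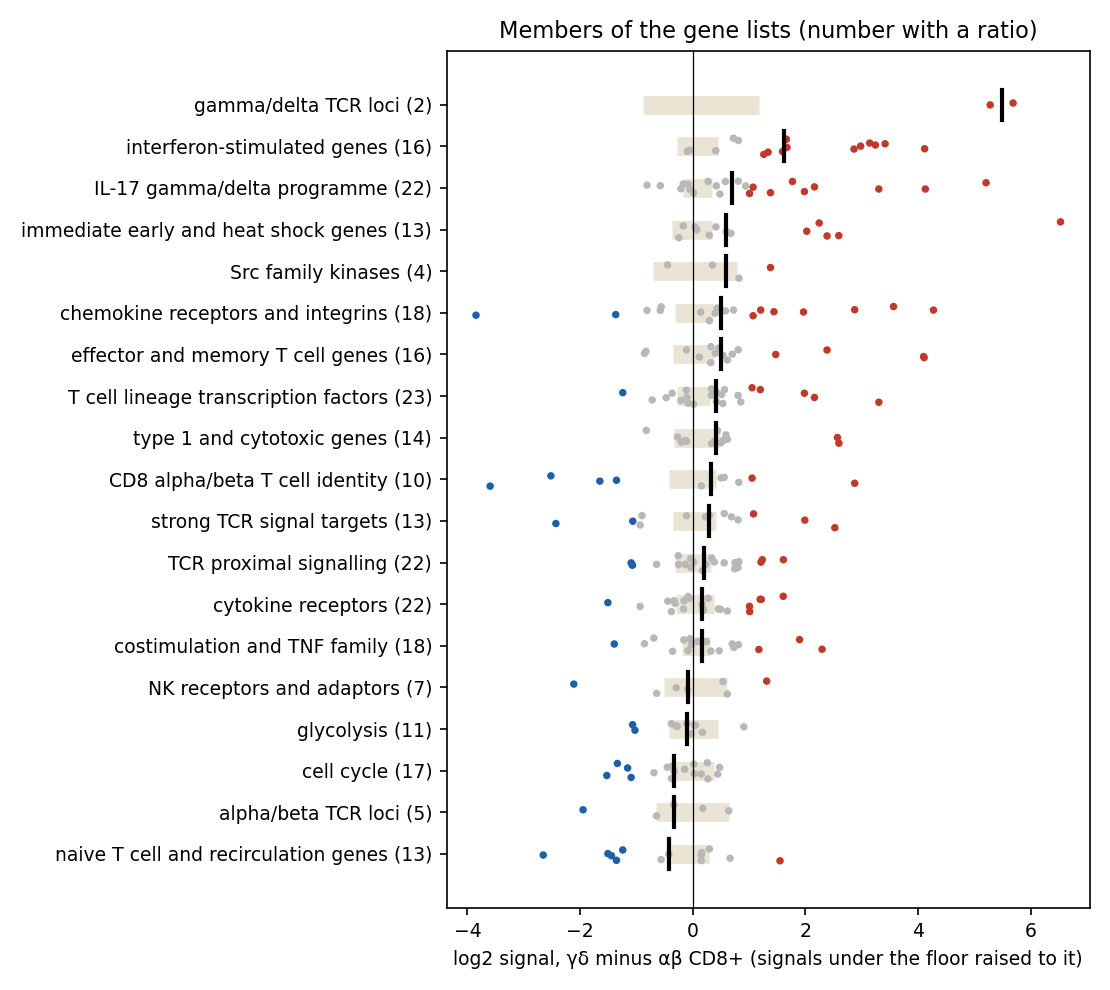
log2 signal of gamma/delta minus alpha/beta CD8+ (horizontal) for the members of 19 gene lists (rows, with the number of members that have a ratio); 1 point per gene, red at least 2-fold higher in gamma/delta, blue at least 2-fold higher in alpha/beta, black bars the list medians, and tan bars the central 95% of medians of 10000 matched random lists. The medians of the interferon-stimulated genes (1.63) and of the IL-17 programme (0.69) lie to the right of their tan bars.

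Of 61 markers of B cells, myeloid cells, erythroid cells and platelets, and stroma, 30 lay under the floor on both arrays by the probe set used and 1 of the 31 with a ratio differed 2-fold, Pou2af1, a transcriptional coactivator of B cells (2.89-fold higher in gamma/delta cells). The medians were 0.29 for B cells, 0.06 for myeloid and dendritic cells, -0.04 for erythroid cells and platelets and -0.06 for stroma and endothelium. Of the 14 B cell markers with a ratio 9 were above 0, and the list lay at the 91.7th percentile. Cd72, Blnk and Ms4a1 had log2 ratios of 0.54, 0.51 and 0.48, Ighm one of 0.38 with probe sets from -0.28 to 1.21, and Ly6d and H2-Aa had -0.78 and -0.73. Cd79a and Cd74 had signals of 43.5 and 146.1 on the gamma/delta array, under the floor. In the NK cell list (median 0.37) Gzma alone reached 2-fold, and Ncr1 and Tyrobp lay under the floor on both arrays. In the list of helper and regulatory T cells (median 0.45) Ikzf2 alone did, and Foxp3 lay under the floor on both arrays. Of the innate lymphoid cell markers Il7r alone did, lower in gamma/delta cells, and its list's median of 0.26 and mean of -0.15 differed in sign.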

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

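The tests of heat shock genes and of T cell receptor targets below were chosen after the results were seen. Probe sets that name no gene here, and so stand outside the comparisons of genes, carried differences too. Among 9160 that the annotation did not list, 151 were at least 2-fold higher in gamma/delta cells and 151 at least 2-fold higher in alpha/beta cells. Of 932 with several symbols, 28 were higher in gamma/delta and 16 in alpha/beta cells. The largest log2 ratios of unlisted probe sets were at least 6.08 and 5.42 towards gamma/delta, and -5.29 and -5.01 in the other direction.

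Blk was higher in gamma/delta cells by a log2 ratio of at least 1.38. RNA of B cells left in the preparation is argued against as the whole cause: the 14 B cell markers with a ratio, 0 of them in another list, had a median of 0.29 (median absolute deviation 0.24), and Cd79a, Cd74 and Igk, which B cells make in abundance, were under the floor on both arrays, although 9 of the 14 were above 0 and Pou2af1 had a log2 ratio of 1.53. Measurement noise stays open. Of 2099 genes whose brighter signal lay between 506.1 and 790.9, around that of Blk, 3.05% (64 genes, exact 95% interval 2.36% to 3.88%) differed by as much, 41 towards gamma/delta and 23 towards alpha/beta. Genes in this window with a brighter signal under Blk's 632.7 could not reach its ratio, because the floor caps theirs, so the share was held low. The interval also treats genes of 1 pair of arrays as independent. The share met the bound of under 5% that was to exclude noise, but that bound was wrong for a gene named in the series title, which may have been picked on these arrays and could be 1 of those 41. The bound was made stricter after the value was seen, and a difference between the lineages stays open beside noise.

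The IL-17 programme was higher in gamma/delta cells by a median log2 ratio of 0.69. Cells with CD44 left in the preparation, which the labelled CD44-negative purification would remove, could bring such genes. The effector and memory list had a median of 0.49, with 13 of 16 genes above 0 and 6 of the 16 in other lists too, and Cd44 a ratio of 0.32 with probe sets of both signs, between the values this explanation needs (1 or more) and those that would exclude it (0 or less). A difference between the lineages themselves also stays open.

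The immediate early genes Fos, Jun, Dusp1, Junb and Fosb were at least 2-fold higher in gamma/delta cells, Fos by a log2 ratio of 6.53, while Zfp36, Btg2 and Ier2 were not. For stress with a heat shock response, the 5 heat shock genes with a ratio had a median of 0.29 (median absolute deviation 0.22), short of 2-fold as a set. The bound of this test was written after these values were seen, so it is no independent evidence and the explanation is not excluded. Stronger T cell receptor signals in the gamma/delta cells remain possible: their targets lay at the 89.7th percentile, with members on both sides of 0. Handling of different length that induces these genes alone was not tested and stays open.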

How the results depend on the processing

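The floor at the brightest empty control was chosen after seeing the data. No result has a replicate, so the alternatives show only how far values depend on choices. The counts of genes at least 2-fold higher in gamma/delta and in alpha/beta cells (693 and 468) were 1320 and 1008 with the floor at the 30th percentile, 396 and 284 at the 70th and 2917 and 2593 with no floor. They were 1033 and 722 with the floor at the brightest empty control. With probe sets averaged both counts fell, to 459 and 322, and the cause was not tested. At 1.5-, 3- and 4-fold the counts were 2025 and 1578, 177 and 72, and 81 and 22. The 3 scalings left both counts within 1.5 times and all 68 called genes named by the rule past 2-fold. The log2 ratio of Blk was at least 2.29, 0.50 and 1.92 with the floor at the 30th and 70th percentile and at the brightest empty control, bounds set by the floor. With no floor it was 6.24, against a signal below the brightest empty control and so no measured ratio. The median of the gamma/delta receptor segments was at least 6.19, 4.60 and 6.01 under the same floors, 7.81 with none, likewise no measured ratio since Trgv1 lies below the brightest empty control in alpha/beta cells, and 3.95 with probe sets averaged. Ccr9 reversed to -0.20 without probe sets ending in _x_at, _s_at or _a_at, which reads it by another probe set, and under which the gamma/delta receptor list has no value. Of the 68 called genes named by the rule, 60 kept the call with the 70th percentile floor (not Anxa2, Bhlhe40, Blk, Ccna2, Ifnar2, Il12rb1, Ptpn6 and Tnfrsf18) and 55 with probe sets averaged (not Anxa2, Ccna2, Ifnar2, Ikzf2, Itgb3, Mcm3, Mcm6, Nr4a3, Ptpn6, Slc2a3, Slfn1, Sox4 and Tnfsf11). Without those probe sets 52 did, as Ccr9 and Mcm3 lost it and the other 14 had no ratio. Genes named beyond the rule were left out of these counts. Among them Ccr6, Il1r1, Il10ra, Txk and Tec also fell short of 2-fold with the 70th percentile floor. The medians of the lists outside the central 95% of random lists kept their sign under every alternative with a value. Beside the receptor segments they ran from 0.35 to 1.31 for immediate early and heat shock genes, 1.30 to 1.76 for interferon, 0.42 to 0.92 for IL-17, 0.29 to 0.55 for chemokine receptors and integrins, 0.32 to 0.61 for effector and memory, 0.33 to 0.42 for transcription factors, -0.57 to -0.21 for naive and -0.43 to -0.14 for cell cycle. The interferon list lay at the 100th percentile under each and the IL-17 list at 99.8 or above. Inside the central 95% under at least 1 alternative came the naive list (up to 6.90), cell cycle (up to 14.1), effector and memory (down to 93.0), chemokine receptors and integrins (94.7), immediate early (95.8) and transcription factors (96.6). No paired analysis was possible because each group has 1 sample. Signal over background limits genes near the floor.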

Other observations

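The lists of FoxO targets, thymocyte genes and circadian clock genes were drawn up after the data had been seen, without the genes that prompted them. The genes named here were chosen after their values were seen. For all 3 tests the value met the bound that was to exclude the explanation, and the rule was then made stricter for the reasons given at each.

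Among genes higher in alpha/beta cells were Klhl24 (4.75-fold), Ccng2 (4.46-fold), Il7r, Klf3 and Bach2, which lower activity of FoxO transcription factors in gamma/delta cells might account for. Of 12 other FoxO targets with a ratio, Tob1 (3.08-fold), Sesn3 (2.74-fold, with probe sets of both signs) and Sesn1 (2.41-fold) were at least 2-fold higher in alpha/beta cells and 0 at least 2-fold higher in gamma/delta cells. The list's median of -0.33 lay at the 7.91th percentile, short of the lowest 2.5% predicted. The miss excludes nothing, since 5 members were above 0 and 7 below and the bootstrap interval of the median ran from -1.08 to 0.20. Foxo1 itself had a log2 ratio of 0.66 towards gamma/delta, with probe sets from 0.38 to 0.85, but its RNA does not measure its activity. The homing genes S1pr1, Klf2 and Ccr7, which were not in the list, had log2 ratios of 0.29, 0.16 and -0.56.

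Dntt, Ccr9, Itgae and Sox4 were higher in gamma/delta cells, which might follow from recent export from the thymus. Of the thymocyte genes, Rag1 and Rag2 lay under the floor on both arrays, 2 of the 8 with a ratio were above 0 (Cd24a with 0.78 and Cd1d1 with 0.69) and 6 below, and the list's median of -0.20 lay at the 14.8th percentile, against the prediction of the top of the range. With 5 genes above the floor on both arrays and a bootstrap interval of the median from -0.41 to 0.69, the explanation is not excluded.

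Nr1d2, a repressor of the circadian clock, was 4.03-fold higher in alpha/beta cells, which could come from a different phase of the circadian clock at harvest. Of 10 other clock genes with a ratio, 1 differed 2-fold (Cry1, 2.23-fold higher in alpha/beta cells), where the prediction was at least 2. A count on the bound and not beyond it leaves the phase open, and Nr1d1 was under the floor on the gamma/delta array.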
